A study of Mus musculus with 2 samples.

How the data were processed

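DNase-seq measures where chromatin is open: nuclei are treated with the nuclease DNase I, which cuts accessible DNA, and the cut ends are sequenced. The samples were 2 libraries of naive resting CD8-positive alpha-beta T cells from male adult B6CASTF1/J mice, a cross of 2 inbred strains, at 2 months of age per the labels. The labels number them biological replicates 2 and 3, each with technical replicate 1, and those numbers name the libraries throughout. Both carry the same donor label and different biosample labels, so whether they came from separate animals is not given in the sources used here. Any p-value below therefore describes these 2 libraries.

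Each library came with 2 peak lists, 1 list of false discovery rates and 1 list of footprints, all on the mm10 build per the labels. Per the notes deposited with each library, every list was made from that library's own alignments and not from pooled libraries. The aligner, the peak caller and the footprint caller are not given in the sources used here. The authors' peak lists hold a signal value for each peak, whose scaling the labels do not state. Within a library, all signal values below 2 were whole multiples of 1 step, within a tolerance of 0.05 of the step (25650 of 25650 values in the stricter list of replicate 2 and 4539 of 4539 in that of replicate 3). If the signal was scaled to tags per 1e+06, that step corresponds to 1.34e+08 tags in replicate 2 and 2.21e+07 in replicate 3. The authors' deposited q-values (false discovery rates per stretch of positions) ran up to 0.05. Every peak of the shorter list of each library held a position with a false discovery rate of at most 0.001, and every peak of the longer list one of at most 0.05. The shorter list is called the stricter list and was used for the main results. The longer one is called the permissive list. Footprints are short stretches protected from cutting inside open chromatin; the deposited lists carry 1 constant in their value column, so only the intervals were used.

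Chromosome lengths of the GRCm38 reference sequence matched mm10. Genes were the protein-coding genes of the GENCODE M21 basic annotation, 21827 symbols in all. A promoter was the window of 1000 bp either side of a protein-coding transcription start site, and these windows covered 1.97% of the genome. Peaks overlapped when they shared 1 bp or more, and a region found in both libraries was an overlap of stricter peaks from each. Overlap was set beside 100 circular shifts of 1 list along its chromosomes. Shares carry Wilson 95% intervals, which cover counting error only. A distal peak overlapped no promoter window, and a locus was the gene body with 10 kb either side.

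The 11 gene lists, the 24 consensus motifs, the tests and most alternatives were fixed before the data were examined. Promoter peaks in both libraries were compared per list with the 21563 protein-coding genes in no list by Fisher's exact test, two-sided. Distal regions per locus were compared with 10000 random lists matched on the decile of gene length, two-sided. Both families were adjusted by Benjamini-Hochberg over the 11 lists, with a threshold of 0.05. Both tests treat genes as independent. Some lists hold neighbouring genes, such as the Klr genes of the gamma-delta and NK list, and neighbouring loci can share a distal region. The p-values may therefore be too small. The B cell list had 22 measured members of 24, and the other 10 lists were measured whole. Motif matches were counted in footprints extended by 5 bp and in windows of the same width centred 100 bp to each side that overlapped no footprint. Their ratio per bp has a 95% Poisson interval and no p-value. The genes named were set by a rule: 22 genes always, and from each list the 4 with the highest mean signal rank among those with a promoter peak in both libraries and up to 3, in alphabetical order, with none in either. The 5 peaks of highest mean rank and the 10 loci with most distal regions were also named. A few genes that this rule selects are not reported here. With 1 group of 2 libraries there was no comparison between groups.

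Alternatives changed the peak list, the number of peaks, the required overlap, the promoter window, the locus flank, the control distance of motifs and the libraries used. The statistics were tested on simulated data. Fisher's test found 98.0% of 200 simulated lists with a share of 80% against 40% among 20000 genes, and passed 3.50% of 200 lists with no difference. The random-list test passed 3.00% of 100 lists with no difference. All simulated lists had 25 genes, so these rates do not describe the CD8 list of 5 genes. Counts in the random-list simulation were independent Poisson draws, denser than the distal regions per locus in these data. The simulated rate is therefore not the error rate of the distal test. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and bedtools 2.31.1, and figures used matplotlib 3.10.9.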

Results

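Open chromatin was mapped by DNase-seq in naive resting CD8 T cells, the circulating precursors of cytotoxic T cells that have not yet met antigen. The data were 2 libraries of 1 group. The stricter list of replicate 2 held 38223 peaks covering 8.35 Mb, and that of replicate 3 held 17061 peaks covering 3.35 Mb. The mean was 27642 ± 14964 peaks (SD, n = 2). The median peak was 200 bp wide in replicate 2 and 180 bp in replicate 3. If the signal was scaled to sequencing depth, replicate 2 was 6.05 times as deep as replicate 3, so a peak's absence from replicate 3 does not show that the site was closed.

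The stricter peaks of replicate 3 were nearly all present in replicate 2. Of the 17061 stricter peaks of replicate 3, 16335 (95.7%, Wilson 95% interval 95.4 to 96.0) overlapped a stricter peak of replicate 2, against a mean of 0.610% over 100 shifts. In the other direction, 42.5% of the peaks of replicate 2 (95% interval 42.0 to 43.0) were found in replicate 3. With the 17061 strongest peaks of each library the overlap was 79.5%. Detection rose with signal: 1.49% of the weakest decile of replicate 2 peaks and 99.2% of the strongest decile were in the stricter list of replicate 3. Across the 16335 overlapping peaks, the Spearman correlation between the libraries' signals was 0.924, a description across peaks that are not independent replicates. The correlation was 0.927 across 9798 promoter peaks and 0.854 across 6537 distal peaks.

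**Figure D1:**
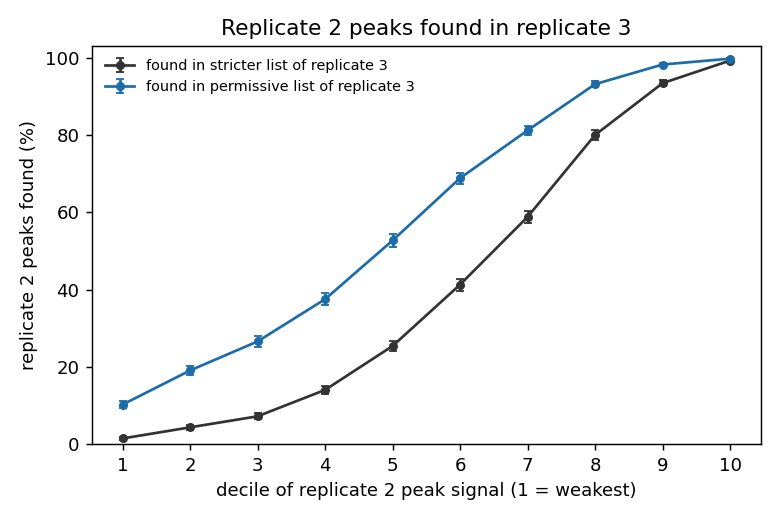
Share of replicate 2 stricter peaks (y axis, %) found in the stricter or the permissive list of replicate 3, by decile of replicate 2 signal (x axis), with Wilson 95% intervals. The share in the stricter list goes from 1.49% in the weakest decile to 99.2% in the strongest.

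**Figure D2:**
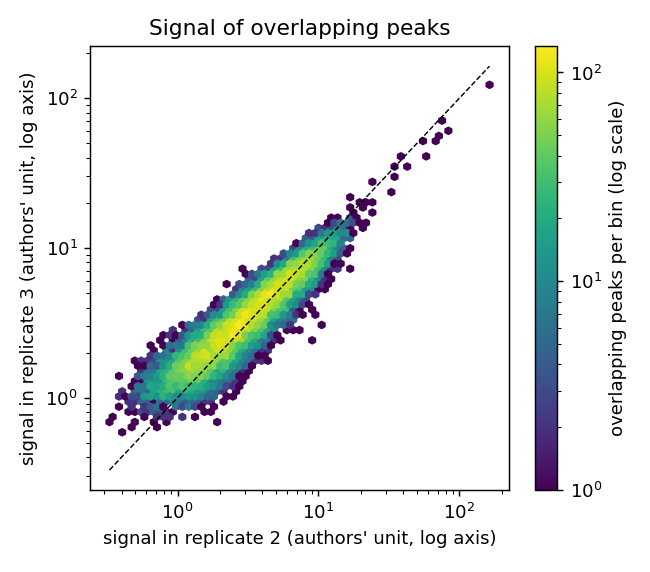
Authors' signal of the 16335 overlapping stricter peaks in replicate 2 (x axis, log) and replicate 3 (y axis, log), coloured by the number of peaks per bin; the dashed line marks equal values. The Spearman correlation was 0.924.

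Promoters made up 42.8% of the peaks of replicate 2 (95% interval 42.3 to 43.3) and 61.1% of those of replicate 3 (60.3 to 61.8), a mean of 51.9% ± 12.9 (SD, n = 2). The promoter windows covered 1.97% of the genome. Among the 15839 regions found in both libraries, 59.3% lay at promoters, 15.2% in introns, 3.71% in exons and 21.7% between genes. The 21970 peaks of replicate 2 not found in replicate 3 were placed differently, with 30.1% at promoters, 31.6% in introns and 32.7% between genes. At equal numbers of peaks, the promoter share was 57.7% in replicate 2. A promoter peak was present in both libraries for 8917 of 21827 protein-coding genes (40.9%), in replicate 2 alone for 2102 and in replicate 3 alone for 7.

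Promoters of housekeeping genes mostly had a peak in both libraries, and promoters of genes of other lineages mostly did not. A promoter peak in both libraries was found for 28 of 30 housekeeping genes (93.3%), against 41.1% of genes in no list (odds ratio 20.1, 95% interval 5.07 to 174, adjusted p = 2.67e-08, Fisher's exact test). Actb had a promoter signal of 15.95 in replicate 2 and 13.2 in replicate 3, Polr2a 14.2 and 9.85, Rplp0 12.6 and 11.4, and Psmb2 10.1 and 10.5. The lists that passed the threshold below the genes in no list were CD4 and helper T cell with 1 of 18 (adjusted p = 0.00239, Fisher's exact test), gamma-delta and NK cell with 0 of 14 (0.00153), B cell with 2 of 22 (0.00275), myeloid with 1 of 26 (9.87e-05), erythroid and megakaryocyte with 0 of 18 (0.000305) and non-haematopoietic tissue with 4 of 46 (8.38e-06). The p-values in parentheses are all Benjamini-Hochberg adjusted. Of the lists that differed, only the myeloid and housekeeping lists also passed when the comparison genes were matched on promoter CpG content (adjusted p = 0.0264, n = 26 genes, and 0.00220, n = 30 genes, the latter from the smallest p that 10000 random lists can give), a comparison chosen after the data were seen.

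The members of these low lists that were open in both libraries were few. Icos, a costimulatory receptor, was the 1 member of the CD4 and helper list, with promoter signals of 3.03 and 2.12 in replicates 2 and 3. In the B cell list they were Pou2af1, a coactivator (3.61 and 2.67), and Cr2, a complement receptor (1.22 and 1.26). Cebpa, a myeloid transcription factor, had 1.28 and 1.40. Among genes of other tissues they were Col1a1 (2.28 and 2.94), Krt10 (1.90 and 1.99), Syp (1.32 and 2.48) and Cdh1 (0.970 and 1.31). No stricter promoter peak was found in either library for Cd4, Ccr6 and Cd40lg of the CD4 and helper list, for Blk, Cd163l1 and Fcer1g of the gamma-delta and NK list, or for Bank1 and Blnk of the B cell list. The same held for the myeloid genes Adgre1, C1qa and C1qb, the erythroid genes Alas2, Ermap and Gata1, and for Acta1, Alb and Apoa1. In replicate 2 alone, 3 further members of the CD4 and helper list, 3 of the gamma-delta and NK list, 4 of the B cell list, 4 of the myeloid list, 3 of the erythroid list and 2 of the non-haematopoietic list had a promoter peak.

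The T cell receptor, CD8 lineage, naive and effector lists did not pass the threshold against genes in no list when a peak was required in both libraries, and the T cell receptor and naive lists did in replicate 2. In both libraries, 7 of 25 T cell receptor and signalling genes (28.0%, adjusted p = 0.274), 2 of 5 CD8 lineage genes (40%, adjusted p = 1) and 11 of 25 naive and memory-precursor genes (44.0%, adjusted p = 0.924) had a promoter peak, by Fisher's exact test. The effector, activation and exhaustion list had 8 of 35 (22.9%, adjusted p = 0.0516, Fisher's exact test). Without replicate 3 the share was, by Fisher's exact test, 80% of the T cell receptor list (adjusted p = 0.00755) and 84.0% of the naive list (adjusted p = 0.00338), against 50.5% of genes in no list. The CD8 list (60%, adjusted p = 1) and the effector list (51.4%, adjusted p = 1) did not pass there by Fisher's exact test. A promoter peak was present in replicate 2 alone for 13 members of the T cell receptor list, 1 of the CD8 list, 10 of the naive list and 10 of the effector list, and in replicate 3 alone for 0 members of any list.

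Among T cell receptor and signalling genes with a promoter peak in both libraries, Rasgrp1, Fyn and Cd28 were among the 4 of highest mean signal rank. Rasgrp1, an activator of Ras, had a signal of 5.50 in replicate 2 and 5.24 in replicate 3. The kinase Fyn had 5.66 and 4.83, and the costimulatory receptor Cd28 had 3.39 and 2.57. The Cd28 signal in replicate 3 was below the median of 3.07 of that library's stricter peaks. Cd2, Lcp2 and Ptprc had no stricter or permissive promoter peak in either library. A missing call does not show that these promoters were closed. In the CD8 list, Runx3, a transcription factor of the CD8 lineage, had 6.95 and 4.25, and Cd8b1, which encodes the beta chain of the CD8 coreceptor, had 4.17 and 3.16, while Cd8a and Itgae had no stricter promoter peak. The permissive list of replicate 2 held one at Cd8a, at 71373364 to 71373564 (1.18, with 4 footprints in the promoter). Klf2, a transcription factor that maintains quiescence and trafficking of naive T cells, had the strongest promoter of the naive list at 14.7 and 13.6. Socs3 had 6.51 and 8.58, Ets1 7.57 and 7.09, and Bach2 6.13 and 6.46, whereas Igfbp4 and Ly6c1 had none. In the effector list the strongest were Nr4a1 (9.02 and 11.2), Entpd1 (6.06 and 6.96), Id2 (6.09 and 4.79) and Prf1, which encodes perforin (3.28 and 3.30). Ccl3, Ccl5 and Cx3cr1 had no stricter promoter peak.

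**Figure D3:**
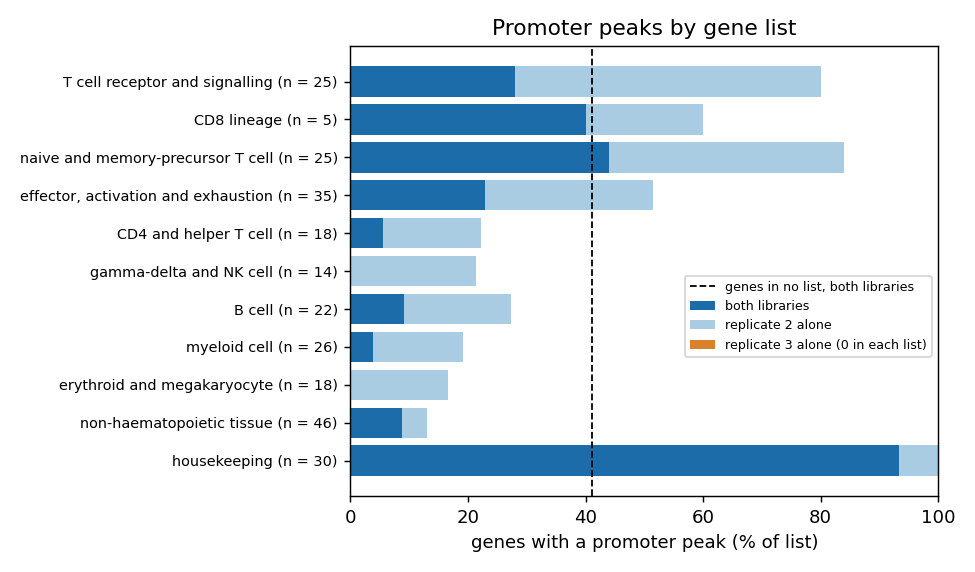
Share of each fixed list's genes (x axis, %) with a stricter promoter peak in both libraries (dark) or in replicate 2 alone (light), with the number of measured genes n; the dashed line is the 41.1% of genes in no list with a peak in both. Housekeeping genes reach 93.3% in both libraries, and the 25 T cell receptor genes have 28.0%.

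At several loci that mark naive CD8 T cells, stricter peaks were called mainly in replicate 2. At Cd8a (chromosome 6, 71373427 to 71379173), replicate 2 had 3 stricter peaks and replicate 3 had 0. They lay between genes at 71369493 to 71369744 (signal 1.94), in an exon with coding and untranslated sequence at 71376868 to 71376942 (1.36) and between genes at 71381704 to 71382002 (1.90). The Cd8b1 promoter peak at 71322381 to 71322833, which also overlapped the promoter of Smyd1, was in both libraries. Ccr7, a homing receptor for lymph nodes, had 14 regions at its locus on chromosome 11 in replicate 2 and 0 in replicate 3. Its promoter peak at 99154981 to 99155420 had a signal of 6.54 in replicate 2 and was absent from the permissive list of replicate 3 too. That list held 3812 of the 3823 peaks in the strongest decile of replicate 2. Lef1, a transcription factor of naive T cells, had 19 regions on chromosome 3, of which 3 were in both libraries, all intronic. They lay at 131157401 to 131157800 (5.15 in replicate 2 and 3.93 in replicate 3), 131208555 to 131208860 (5.13 and 3.93) and 131214961 to 131215160 (2.07 and 2.80). Tcf7 had 5 regions, all in the stricter list of replicate 2 alone. No promoter peak was called at Tcf7 in either list of either library, which does not show a closed promoter. The strongest lay in an intron on chromosome 11 at 52265761 to 52265960 (3.21), and the permissive list of replicate 3 also held it (3.03). Il7r had 5 and Cd3e 4 regions, in the stricter list of replicate 2 alone. The permissive list of replicate 3 held no peak at the Cd8a, Ccr7 and Il7r loci. The Cd3e promoter peak at 45009309 to 45009800 (1.69) and the Lef1 promoter peak at 131111981 to 131112820 (2.93) were in the permissive list of replicate 3 as well (2.03 and 2.48). In the loci of the T cell receptor, CD8 and naive lists, replicate 2 had 358 stricter peaks. Of these, 153 (42.7%) were in the permissive list of replicate 3. Of the replicate 2 peaks outside every listed locus, near a gene or not, 58.9% were.

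**Figure D4:**
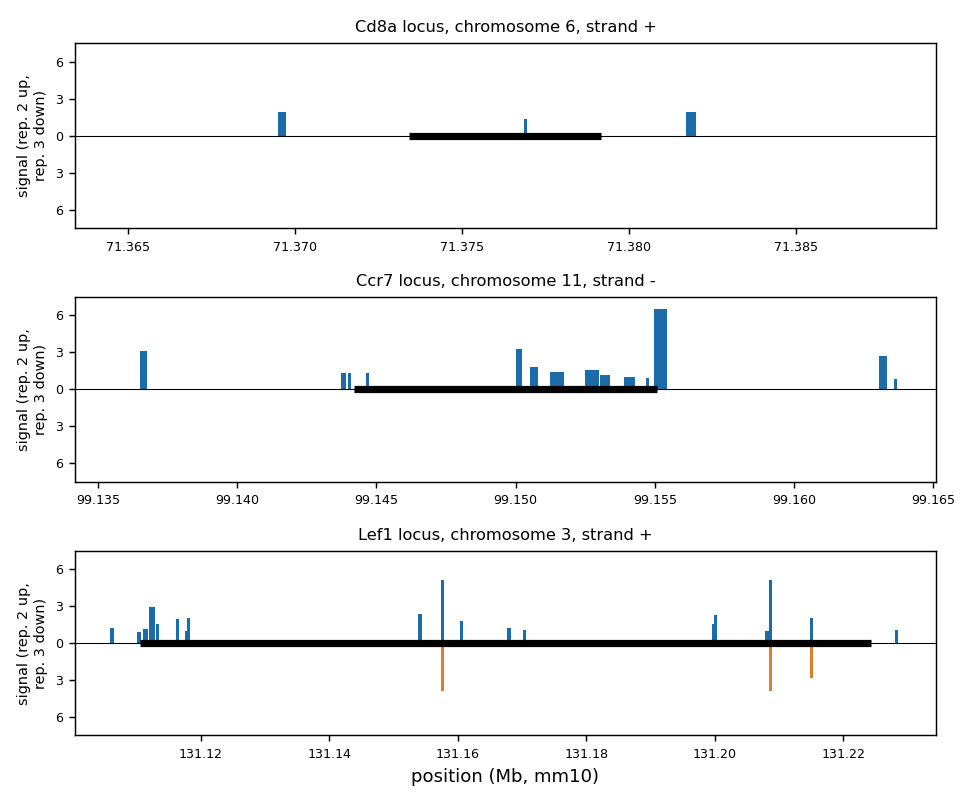
Stricter peaks at the Cd8a, Ccr7 and Lef1 loci (x axis, mm10 position in Mb; gene body as a thick line), with bar height giving the authors' signal in replicate 2 (upward) and replicate 3 (downward); narrow peaks are widened to a minimum drawn width. The Cd8a and Ccr7 loci have 3 and 14 regions in replicate 2 and 0 in replicate 3.

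Of the genes named for effector function, Prf1 had 2 regions in both libraries, at its promoter on chromosome 10 (61297601 to 61297840) and between genes at 61306281 to 61306540. Tbx21 had 1 in both, in coding sequence on chromosome 11 at 97101821 to 97102000. Eomes had 1 in both, between genes on chromosome 9 at 118489721 to 118489920, and Pdcd1 had 2 in both, between genes on chromosome 1 at 94034983 to 94035240 and 94035358 to 94035620. Tox had 9 regions with 2 in both, 1 of them at its promoter on chromosome 4 (6990961 to 6991540). Gzmb had 1 region at its promoter in replicate 2 alone (0.657), and Ifng had 0. The Cd4 locus had 4 regions, of which the 2 in both libraries lay at neighbouring genes, at the P3h3 promoter and in a Gpr162 intron, and the 2 in Cd4 introns were in replicate 2 alone. The 1 region near Foxp3 in both libraries was the Ppp1r3f promoter. Pax5 had 2 regions in both, in introns on chromosome 4 at 44564661 to 44564860 and 44704381 to 44704684. Csf1r, Gata1 and Alb had 0 regions in either library.

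Distal regions were most numerous per locus in the naive and memory-precursor list, but no list passed the adjusted threshold. That list had a mean of 1.08 distal regions per locus, against a median of 0.320 over random lists matched on length (p = 0.00520, adjusted p = 0.0572, n = 25 genes). The effector list had 0.600 against 0.257 (adjusted p = 0.0770, n = 35 genes), the T cell receptor list 0.760 against 0.360 (adjusted p = 0.0979, n = 25) and the myeloid list 0.5 against 0.231 (adjusted p = 0.0979, n = 26). Adjusted p was 0.265 or higher for the other 7 lists, with means of 0.4 for CD8 lineage, 0.5 for CD4 and helper, 0.429 for gamma-delta and NK, 0.455 for B cell, 0.278 for erythroid, 0.391 for non-haematopoietic and 0.267 for housekeeping. All 11 lists lay above their random median, the housekeeping list included. Without replicate 3 the naive list had 5.80 distal peaks per locus (adjusted p = 0.0198, n = 25 genes) and the T cell receptor list 3.88 (adjusted p = 0.0286, n = 25 genes). The loci with most distal regions in both libraries were Gm20388 with 44, Fgfr2 with 13, Cdh23 with 8, Ctif and Wwox with 7, Bach2, Camta1, Rapgef4 and Ssh2 with 6, and Arhgap23, the first in alphabetical order of the loci tied at 5. The first 2 have annotated gene bodies of 4435 kb and 2961 kb.

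The strongest peaks in both libraries lay away from the T cell genes. The first was on chromosome 17 at 39846781 to 39846920, with signals of 164 in replicate 2 and 123 in replicate 3. An annotated rRNA gene lies within 1 kb, and the nearest protein-coding start site, of Esp38, was 104 kb away. The second lay in an untranslated exon of Lars2 on chromosome 9 at 123461901 to 123462120 (78.9 and 69.8), with Limd1 the nearest start site. The third was in an intron of Zc3h7a on chromosome 16 at 11144171 to 11144300 (80.3 and 60.6), nearest to Txndc11. The others were between genes, on chromosome 6 at 49236421 to 49236620, nearest to Igf2bp3 (73.2 and 57.7), and on chromosome 3 at 5860361 to 5860530, nearest to Gm8797 (66.6 and 51.1). Copy number of the sequence and read mapping were not examined, so these peaks are not shown to be the most open sites.

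Footprints were called at 146244 positions in replicate 2 and 29967 in replicate 3, a mean of 88106 ± 82220 (SD, n = 2), with a median width of 9 bp in each. Stricter peaks of the same library held 75.4% of the footprints of replicate 2 and 89.6% of those of replicate 3. Of the footprints of replicate 3, 66.9% (95% interval 66.3 to 67.4) overlapped one of replicate 2, against a mean of 0.121% over 100 shifts. The shifts did not keep footprints inside peaks, so this excess includes the overlap of the peaks themselves. Agreement of footprint positions within peaks was not tested. The overlap was 23.8% when 50% of each footprint had to be shared.

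The CTCF motif, bound by the insulator protein CTCF, had the highest ratio in each library among motifs with 4 or more control matches. Its consensus CCASYAGRKGGC occurred 24.9 times per 1000 footprints in replicate 2 and 20.8 times in replicate 3. The ratio to flanking windows was 304 (95% interval 189 to 522) in replicate 2 and 225 (96.0 to 696) in replicate 3. In both libraries the interval also lay above 1 for NRF1 (134 and 32.1), CREB/ATF (17.1 and 10.2), ETS (7.90 and 3.74), KLF/SP (6.49 and 3.96), NFY (1.40 and 1.73) and the E-box CACGTG (1.52 and 1.34), giving 7 of 24 motifs. It lay below 1 in both for ZEB (0.520 and 0.392), FOXO (0.403 and 0.380), GATA (0.384 and 0.353) and NFAT (0.645 and 0.292). RUNX had a ratio of 2.02 (1.73 to 2.37) in replicate 2, and its interval in replicate 3 covered 1 (1.26, 0.707 to 2.21). TCF7/LEF1 had intervals that covered 1 in both (1.13 and 0.713). YY1 stood at 3.73 (2.54 to 5.57) in replicate 2 and 0.560 (0.276 to 1.06) in replicate 3. ISRE/IRF (2.28, 1.75 to 2.99) and the KLF GT-box (1.38, 1.19 to 1.61) also lay above 1 in replicate 2 alone. PU.1, the motif of a B cell and myeloid factor, did so in replicate 3 alone (4.22, 1.52 to 13.4, from 14 footprint and 6 control matches). Its consensus AGAGGAAGTG shares GGAAGT with the ETS consensus ACCGGAAGT, so these matches do not single out PU.1. Footprints of replicate 2 held 61.3% G and C against 53.8% in the flanking windows, and those of replicate 3 held 65.5% against 59.6%. Ratios of motifs rich in G and C include that difference. So do the low ratios of motifs rich in A and T, such as FOXO, GATA and NFAT.

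**Figure D5:**
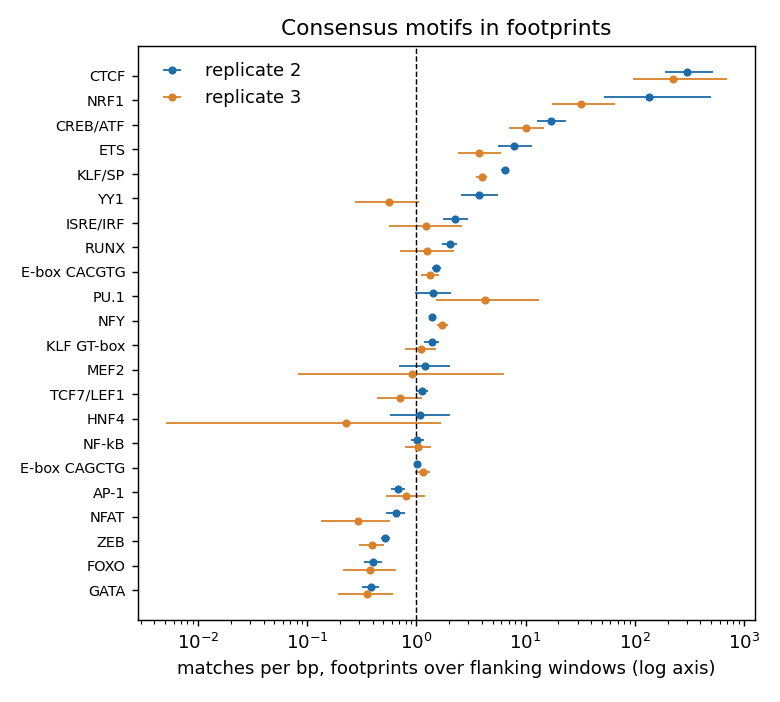
Ratio of consensus matches per bp in footprints to flanking windows (x axis, log) for motifs with 4 or more control matches, in replicate 2 (blue) and replicate 3 (orange), with 95% Poisson intervals; the dashed line marks 1. CTCF is highest at 304 and 225.

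Peaks were sparser on the X chromosome than on autosomes. Replicate 2 had 15.1 peaks per Mb on autosomes, 6.15 on X and 0.414 on Y, and replicate 3 had 6.78, 2.13 and 0.0763. The ratio of X to autosomes was 0.408 in replicate 2 and 0.314 in replicate 3, a mean of 0.361 ± 0.0661 (SD, n = 2). Copy number and gene density were not corrected for in these male mice, so less open chromatin on X is not shown. On Y, 7 regions were in both libraries. They included 2 at the Eif2s3y promoter (1010221 to 1010440 and 1010461 to 1010680) and 1 each at the promoters of Uty (1245654 to 1245880) and Ddx3y (1286441 to 1286720).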

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

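The false discovery rate lists were used only to order the peak lists, and they hold low rates outside every permissive peak. Replicate 2 had 14749 stretches with a rate of 0.001 or below outside its permissive peaks, 22.5% of all such stretches, and replicate 3 had 6261, 22.6%. Outside peaks the median stretch was 3 bp in replicate 2 and 5 bp in replicate 3, against 185 bp and 180 bp for stretches in peaks. A permissive peak lay within 150 bp of 8257 of the outside stretches in replicate 2 (56.0%) and of 4383 in replicate 3.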

How the results depend on the processing

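Comparisons with CpG-matched or neighbourhood-matched genes, the permissive list of replicate 2 alone and the peaks low in repeats were chosen after the data were seen; the other alternatives were set before. The cause was not tested for any change below except that leaving out replicate 3 removes the library with fewer peaks.

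Peaks per library averaged 13821 with the stronger 50% of peaks and ran from 17061 to 38223 with 1 library left out. Peak overlap was 93.4% with the permissive list, 79.5% at equal numbers, 80.1% with 50% reciprocal overlap, 99.1% with the stronger 50% and 93.8% with peaks of at most 20% repeat bases. The Spearman correlation was 0.927 with the permissive list and 0.900 at equal numbers. Footprints ran from 29967 to 146244 with 1 library left out, and their overlap was 23.8% with 50% reciprocal overlap and 68.0% inside regions found in both libraries. The motifs with an interval above 1 numbered 8 to 11 with 1 library left out and 6 with control windows at 50 bp, against 7 in the main setting. The promoter share and the ratio of X to autosomes moved by less than 1 SD under the alternatives that kept both libraries. With 2 libraries, leaving out either moves a mean by less than 1 SD whatever the data, so that says nothing about these results.

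For promoter peaks, leaving out 1 library gave 28.0% to 80% of the T cell receptor list, 40% to 60% of the CD8 list, 44.0% to 84.0% of the naive list and 22.9% to 51.4% of the effector list. The permissive list gave 48.0% of the T cell receptor list, turning its direction, 72.0% of the naive list, now past the threshold (adjusted p = 0.0178, Fisher's exact test), and 21.4% of the gamma-delta and NK list, no longer past it. The effector list passed at equal numbers (20%) and with the 2500 bp window (22.9%), and the CD8 list (40%) turned at equal numbers. With the permissive list of replicate 2 alone the shares were 84.0% for T cell receptor, 80% for CD8, 88.0% for naive and 71.4% for effector genes, and 35.7% for gamma-delta and NK and 36.4% for B cell genes, which no longer passed. Against CpG-matched genes the lists at 5.56% (CD4 and helper), 0% (gamma-delta and NK), 9.09% (B cell), 0% (erythroid) and 8.70% (non-haematopoietic) no longer passed. The T cell receptor (28.0%) and CD8 (40%) lists then lay above the matched median and the naive list (44.0%) below it, with no call.

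For distal regions, no list passed in the main setting. The T cell receptor list passed with the permissive list (1.80 per locus), a 50 kb flank (1.56) and the permissive list of replicate 2 alone (5.28), and ran from 0.760 to 3.88 with 1 library left out. The naive list did so too (2.28, 2.48 and 9.04), running from 1.20 to 5.80. With the 50 kb flank the effector (1.43), myeloid (1.73) and housekeeping (1.30) lists passed. With the permissive list of replicate 2 alone the CD8 (3.80) and effector (2.71) lists passed and the erythroid list (0.722) fell below its random median. Matched on neighbourhood, 10 of 11 lists stayed above their random median and none passed.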

Other observations

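Tests of the T cell loci missing from replicate 3, their bootstrap over loci and the neighbourhood-matched comparison were chosen after the result was seen.

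Motif frequencies differed between footprints away from promoters and those at promoters. In replicate 2, CTCF matched 46.2 times per 1000 distal footprints and 2.95 times per 1000 promoter footprints, a ratio of 15.7 (95% Poisson interval 13.7 to 18.1), and in replicate 3 the ratio was 15.7 (12.5 to 19.97). RUNX, the motif of factors that act in T cell development, was 6.59 times as frequent in distal as in promoter footprints of replicate 2 (4.88 to 9.05) and 2.71 times in replicate 3 (1.09 to 6.78). Its ratio to flanking windows in replicate 2 was 2.46 (2.07 to 2.92) for distal and 1.25 (0.826 to 1.90) for promoter footprints. In replicate 3 both intervals covered 1 (1.21 and 1.39), so there the excess is not shown to be one of footprints over their surroundings. KLF/SP matches went the other way, at 0.117 (0.104 to 0.132) and 0.131 (0.0937 to 0.179), as did NFY at 0.301 (0.267 to 0.338) and 0.284 (0.210 to 0.377). Against flanking windows, NFY in distal footprints had intervals that covered 1 in both libraries (0.918, 0.805 to 1.05, and 1.29, 0.898 to 1.85). In promoter footprints they lay above 1 (1.55 and 1.77). TCF7/LEF1 was 2.85 times as frequent in distal footprints of replicate 2 (2.29 to 3.58), and its interval in replicate 3 covered 1 (1.55, 0.630 to 3.64). Against flanking windows it stood at 1.26 (1.08 to 1.46) in distal and 1.05 (0.802 to 1.37) in promoter footprints of replicate 2, and at 0.737 (0.317 to 1.58) and 0.707 (0.370 to 1.29) in replicate 3. GATA (4.04), PU.1 (3.79), AP-1 (2.95) and ZEB (2.74) were also more frequent in distal footprints of replicate 2, although GATA, AP-1 and ZEB lay below their flanking windows there (0.448, 0.762 and 0.738). The PU.1 motif, which shares GGAAGT with that of ETS, does not single out PU.1. It lay above its flanking windows in distal footprints of both libraries (1.74, 1.13 to 2.68, and 5.75, 1.43 to 33.0). A distal excess in frequency therefore need not be enrichment in footprints.

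The larger number of peaks in replicate 2 went with signal. Of its strongest decile, 99.7% were found among the permissive peaks of replicate 3, and of its weakest decile 10.3%, which is consistent with sequencing depth. Cells of other blood lineages in replicate 2 stay open: among genes with no promoter peak in replicate 3, 11 of 63 B cell, myeloid and erythroid genes had one in replicate 2, against 16.1% of genes in no list (odds ratio 1.10, 95% interval 0.517 to 2.14). No biological difference between groups was tested, as the design has 1 group.

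Peaks at T cell loci were found in replicate 3 less often than peaks matched on signal and promoter class. In the loci of the T cell receptor, CD8 and naive lists, 153 of 358 stricter peaks of replicate 2 were in the permissive list of replicate 3. Comparison peaks were all those outside every listed locus, near a gene or not. Against matched peaks of these, the odds ratio of being found was 0.282 (95% interval 0.214 to 0.371). That argues against sequencing depth as the whole cause only as far as the matching holds. The local background of the peak caller, as far as neighbouring peaks measure it, did not remove this (0.367, 0.278 to 0.484), and diffuse cutting was not measured. Peaks in a locus are not independent, but resampling the 53 loci left found peaks at 0.671 of the matched number (0.570 to 0.766). With neighbours matched too, the value was 0.728 (0.624 to 0.826). Without neighbours matched, it was 0.788 (0.585 to 0.951) for effector, 0.891 (0.750 to 1.02) for housekeeping and 0.953 (0.805 to 1.13) for B cell, myeloid and erythroid loci. Differences between these lists were not tested. The odds ratio itself was also below 1 for effector (0.384, 0.234 to 0.632) and housekeeping loci (0.417, 0.228 to 0.764). Its interval covered 1 for B cell, myeloid and erythroid loci (0.838, 0.531 to 1.32) and for non-haematopoietic loci (1.10, 0.533 to 2.25). Resampling the non-haematopoietic loci, without neighbours matched, gave 1.02 (0.888 to 1.15). As the housekeeping odds ratio was below 1, the pattern is not shown to be peculiar to T cell genes. The resampled housekeeping interval covered 1, however. The matching may leave a depth effect at some loci, though not at every listed set, so depth is not excluded. A weaker signal at T cell genes in replicate 3 stays open. The median signal ratio of peaks there found in both libraries was 1.03 (central 95% of matched draws 1.01 to 1.14), but it leaves out the peaks missing from replicate 3 and so cannot decide this.

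As a pool, promoters of other lineages had peaks in both libraries less often than their CpG content accounts for. Of the pooled B cell, myeloid, erythroid and non-haematopoietic genes, 6.25% had a promoter peak in both libraries, below the central 95% of CpG-matched lists (12.5% to 24.1%), which argues against CpG content as the whole cause for the pool. Of the 4 lists on their own, only the myeloid list passed after adjustment, and the B cell (9.09%) and erythroid (0%) lists lay inside their matched ranges (0% to 27.3% and 0% to 27.8%). Their distal regions were not fewer than in length-matched lists: the mean of 0.411 per locus lay above the central 95% (0.143 to 0.348). Matched on neighbourhood as well, it lay inside (0.188 to 0.420, p = 0.0638, n = 112 genes).

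T cell receptor loci had 3.10 times as many regions per Mb found in both libraries as immunoglobulin loci, with an interval that covers 1 (0.942 to 10.8, from 8 and 6 regions). At 3.03 per Mb they lay below the genome as a whole (5.81). In replicate 2 the ratio was 2.16, from 39 and 42 peaks, and the T cell receptor loci had 14.8 peaks per Mb against 14.02 in the genome. Of regions in both libraries, Igh had 6 over 2.76 Mb, Igk 0 over 3.17 Mb and Igl 0. Tra/Trd had 4 over 1.80 Mb, Trb 4 over 0.667 Mb and Trg 0, so the pooled ratio does not hold for each locus. The 100 strongest peaks found in both libraries held 8.74% soft-masked bases on average, just above the central 95% of random draws (3.84 to 8.64), while the strongest 3 held 0%. Soft-masking was the only repeat measure, so 0% does not exclude sequence present in many copies. Of the strongest 20, the peaks ranked 10, 14, 15 and 17, all on chromosome 9 and singled out after their values were seen, held 97.3% to 100%. Permissive peaks of replicate 2 with 3 or more neighbours within 10 kb were missing from the stricter list more often than those with none at matched signal (odds ratio 3.20, 2.94 to 3.47), although in the weakest decile the order was the opposite and in the strongest decile 0 of 5360 peaks were missing.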
